A study of Homo sapiens with 12 samples.

How the data were processed

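Messenger RNA of MDA-MB-231 cells was sequenced in 12 libraries, 3 for each combination of hairpin (shControl or shRIPOR3) and oxygen level. Per the labels, cells grew in DMEM with 10% serum and 1% penicillin-streptomycin at 37 °C, hypoxia was 1% O2 with 5% CO2 for 24 hours, and stranded mRNA libraries were made from 2 µg of RNA. The authors deposited a table of raw counts per gene symbol with 1 column per library, and nothing in the values pointed to a normalization. The submitters' processing notes name fastp 0.23.4, STAR 2.5.3a, featureCounts without a version and GRCh38, with no role or order. The gene annotation, the strand setting, the treatment of duplicates and the hairpin sequence are not given in the sources used here.

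All 24641 gene symbols were read, 8 of them with a total of 0. Names of 24 symbols had been turned into dates by a spreadsheet, held 0.2% of the counts and were kept as they stood. Symbols were matched as they stood to GENCODE 29, which gave 24045 symbols with 1 gene, 60 with several and 536 with none. RefSeq synonyms served to find members of the gene lists. Library totals and their TMM factors, from 0.9515 to 1.048, set the scale. The depth bounds weak genes most, as for RIPOR3, whose intervals are exact Poisson intervals at 95% and cover counting error only.

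Counts were fitted in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group over all 12 libraries, after filterByExpr left 15648 genes. Quasi-likelihood F-tests gave p-values, adjusted by Benjamini and Hochberg, with a threshold of 0.05, and the biological coefficient of variation was 3.75%. The comparisons were hypoxia against normoxia within each hairpin, shRIPOR3 against shControl within each oxygen level, and the interaction of the 2. Levels of single genes are TMM-normalised CPM, and those of RIPOR3 are CPM of the library total. Replicate numbers were not used as pairs, since libraries with the same number did not correlate across groups (median -0.00402 over 18 pairs).

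Gene lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names RIPOR3, METTL3, HIF1A and EPAS1 throughout. It adds the 8 largest increases and 8 largest decreases in hypoxia in shControl and in each knockdown comparison, and the 5 largest each way in the other 2. These genes had to pass the threshold, reach 5 CPM in the higher group and, outside the interaction, have replicates of the 2 groups that do not overlap, which chance gives in 10% of genes with 3 against 3. From each list it takes up to 4 members with the smallest p. Of 27 lists 26 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and the fry test, and mitochondrially encoded genes, absent from the table, were not analysed here. The lists were HIF targets, glycolysis, oxidative phosphorylation, the tricarboxylic acid cycle, m6A machinery, EGFR and PI3K-AKT components, ERK-responsive genes, FOXO targets, mesenchymal, epithelial, extracellular matrix, G2/M, DNA replication, histone, p53, ATF4, endoplasmic reticulum chaperone, cholesterol synthesis, interferon-stimulated, NF-kB, ribosome biogenesis, ribosomal protein, immediate-early, luminal, and blood and endothelial genes. Results of 1 further tested list and of some genes that the rule takes are not reported here.

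Alternatives were DESeq2 1.42.0, median-of-ratios and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, a replicate block, only the 2 groups compared, a threshold of 0.01 and leaving out each library. Library totals without scaling factors and thinning to one total were added after seeing the data. The pipeline was tested on simulated data with the dispersion of these libraries. It recovered 44% to 72% of the 25 genes evaluated at a 5/4-fold change and 80% to 92% of the 50 changed 2-fold. It called 6 to 17 of 15423 unchanged genes, a planted list in each comparison, and 1 of 26 other lists in 3 of the 5 comparisons. These false calls made up 3.33% of all calls for shRIPOR3 against shControl in normoxia. In the other comparisons they made up 5.18% to 8.63%, more than the main threshold aims for, and were highest for shRIPOR3 against shControl in hypoxia. The simulation changed far fewer genes than the real comparisons called and drew genes independently, so it does not cover scaling shifts or correlated lists. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for sequence searches and figures.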

Results

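RNA sequencing profiled MDA-MB-231 cells, a human triple-negative breast cancer cell line with mesenchymal features, that carried either a control short hairpin RNA (shControl) or a hairpin against RIPOR3 (shRIPOR3). Both lines were kept in normoxia or in hypoxia (1% O2 for 24 hours), which gave 4 groups of 3 libraries. The study addressed what RIPOR3 does in the growth and spread of breast tumours, and its title ties RIPOR3 mRNA to hypoxia and to METTL3, the catalytic subunit of the m6A RNA methyltransferase. The deposited table held counts for 24641 gene symbols, and 15648 of them had enough reads to be tested. Library totals ran from 14750734 to 30032858 counts in normoxia and from 31781324 to 52526813 in hypoxia, so depth differed with the oxygen level. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom between 2.69 and 6.23. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

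RIPOR3 was scarce in these cells, rose under hypoxia and was lower in shRIPOR3 in both oxygen conditions. The gene lies on chromosome 20 from 50586108 to 50691528 on the minus strand (GRCh38). In normoxia the shControl libraries held 7, 3 and 7 RIPOR3 counts, or 0.237 ± 0.0315 CPM (library-size-scaled counts, mean ± SD, n = 3), and the shRIPOR3 libraries held 0, 0 and 1. In hypoxia the shControl libraries held 33, 18 and 30 counts (0.757 ± 0.165 CPM, n = 3) and the shRIPOR3 libraries 9, 3 and 11 (0.156 ± 0.0644 CPM, n = 3). The summed counts gave a ratio of shControl over shRIPOR3 of 4.65 in hypoxia, with a 95% exact Poisson interval of 2.90 to 7.74, and of 16.7 in normoxia, with an interval of 2.62 to 698. Hypoxia over normoxia was 3.15 (1.85 to 5.67) in shControl. In edgeR's quasi-likelihood test the adjusted p of RIPOR3 was 0.0013 for the knockdown in normoxia, 1.69e-06 for the knockdown in hypoxia and 0.000546 for hypoxia in shControl. The intervals cover counting error only. With a single RIPOR3 count in the 3 normoxia shRIPOR3 libraries, the 2 knockdown ratios were not distinguishable (interaction adjusted p = 0.326).

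**Figure D1:**
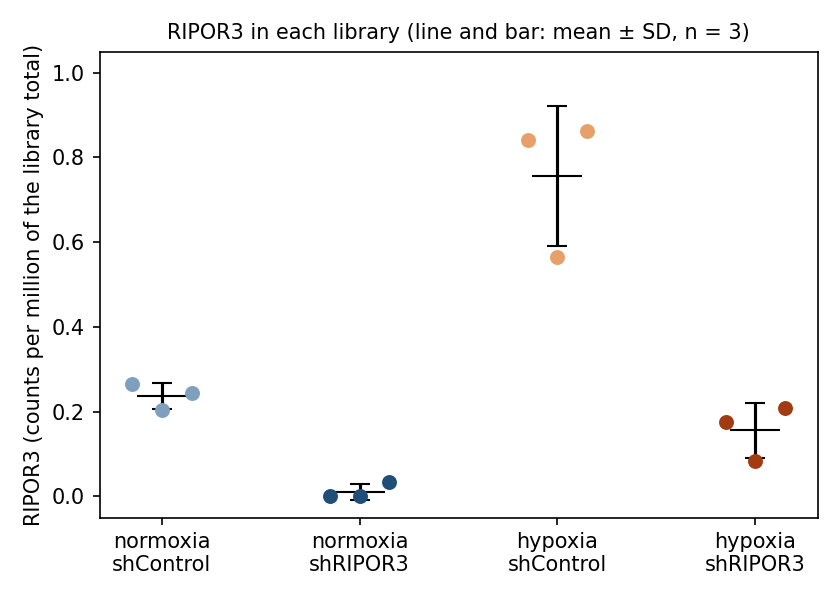
RIPOR3 in CPM of the library total (vertical axis) for each of the 12 libraries, by group, with the mean and SD of each group (n = 3). The hypoxia shControl libraries average 0.757 CPM and the normoxia shRIPOR3 libraries 0.0111 CPM.

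The 12 libraries separated by group. The first principal component of log2 CPM (47.1% of the variance) placed the hypoxia shControl libraries at one end and the normoxia shRIPOR3 libraries at the other. The second component (26.5%) separated the hairpins, with the normoxia shControl libraries at its top.

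**Figure D2:**
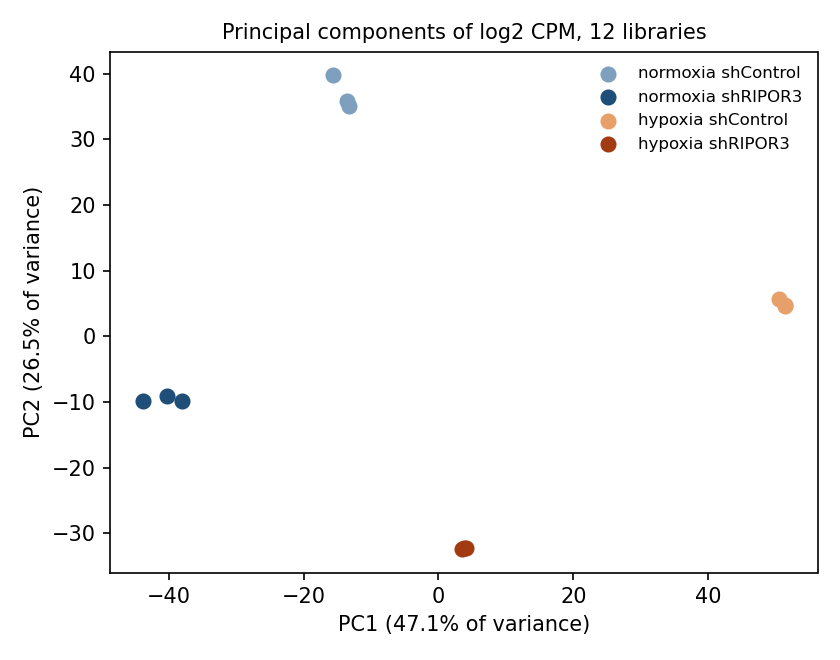
First and second principal components of log2 CPM over the 12 libraries, coloured by group. The axes hold 47.1% and 26.5% of the variance, and each group of 3 libraries forms its own cluster.

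The first comparison asked what hypoxia changed in shControl cells. Genes controlled by the hypoxia-inducible factors (HIF) rose as a block: all 29 targets on the list fixed beforehand rose, with a median log2 fold change of 1.68. NDRG1, a classic hypoxia marker, went from 167 ± 5.00 to 1972 ± 30.7 CPM (mean ± SD, n = 3), a log2 fold change of 3.56 ± 0.0402 (± SE, here and for later log2 values). CA9, the cell-surface carbonic anhydrase, was barely detected in normoxia at 0.136 ± 0.0256 CPM and stood at 15.6 ± 0.729 CPM in hypoxia (log2 6.82 ± 0.185, adjusted p = 1.51e-19). HIF1A mRNA, which encodes the main oxygen-regulated subunit, fell from 180 ± 0.294 to 65.0 ± 2.44 CPM (log2 -1.47 ± 0.0388), whereas EPAS1, which encodes HIF-2 alpha, rose by 1.14 ± 0.069. METTL3 fell by 0.51 on the log2 scale, from 70.8 ± 2.67 to 49.8 ± 1.90 CPM (adjusted p = 7.3e-11). On GRCh38 HIF1A lies on chromosome 14 from 61695513 to 61748259, METTL3 on chromosome 14 from 21498133 to 21511375 and EPAS1 on chromosome 2 from 46293667 to 46386703.

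Among the strongest increases were PPFIA4 (4.73 ± 0.0934), PLA2G4D (4.66 ± 0.213), TCAF2 (4.33 ± 0.226), the lipoprotein lipase inhibitor ANGPTL4 (3.94 ± 0.151), SPAG4 (3.19 ± 0.111) and RASSF4 (3.12 ± 0.0769). The normoxia replicates of TCAF2 were uneven, and its log2 fold change was 5.38 without replicate 3 of normoxia shControl. Under the rule for named genes, the strongest decreases beyond SERF1B and HIF1A were smaller than these increases. They included ID3 (-1.23 ± 0.0954), an inhibitor of basic helix-loop-helix factors, the HSP90 cochaperone CHORDC1 (-1.22 ± 0.0434), RRP9 (-1.18 ± 0.0497), SMARCD3 (-1.16 ± 0.114), the translation factor subunit EIF2B3 (-1.14 ± 0.0498) and COQ3 (-1.11 ± 0.0573), an enzyme of coenzyme Q synthesis. SERF1B, whose reads are hard to tell from those of a near-identical copy, had a log2 fold change of -2.32 ± 0.429 that became -1.23 without replicate 2 of normoxia shControl.

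Metabolic genes moved apart. Of 19 glycolytic genes 17 rose and 1 fell, among them hexokinase HK2 (2.37 ± 0.0391), the glucose transporter SLC2A1 (1.68 ± 0.0393), PGK1 (1.25 ± 0.0359) and ALDOC (3.07 ± 0.0967). Of 27 nuclear-encoded genes of oxidative phosphorylation 25 fell and none rose, including the ATP synthase genes ATP5G1 (-0.92 ± 0.0436) and ATP5A1 (-0.71 ± 0.0351). Of 14 tricarboxylic acid cycle genes 12 fell, such as SUCLG1 (-0.91 ± 0.0389) and IDH3A (-0.77 ± 0.0395). Unless a second count is given, the counts of each list named here were the same when adjusted over the list alone. Genes of the extracellular matrix and its crosslinking rose in 22 of 26 cases (23 adjusted over the list alone), with PLOD2, a collagen lysyl hydroxylase, up by 1.63 ± 0.0375, CTGF by 1.90 ± 0.0377 and COL7A1 by 2.06 ± 0.053. All 28 cytosolic ribosomal protein genes fell (median -0.53), as did 19 of 22 ribosome biogenesis genes, with 1 higher (median -0.43), and 21 of 25 DNA replication genes, with 3 higher (median -0.33; adjusted p = 0.115 with an estimated correlation). Of 24 G2/M genes 18 fell, such as the cyclin CCNB1 (-0.65 ± 0.0339), and 4 rose, among them MKI67 (1.09 ± 0.0366), a list with an adjusted p of 0.0551 with an estimated correlation. Cholesterol synthesis rose in 18 of 23 genes and fell in 4 (adjusted p = 0.101 with an estimated correlation), and the ATF4 list rose in 11 of 19 and fell in 4 (adjusted p = 0.156 with an estimated correlation).

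Across all genes, edgeR called 10142 genes at an adjusted p under 0.05, of which 5074 rose and 5068 fell. Changes of at least 2-fold were lopsided, with 1245 genes up and 112 down, of which 595 and 63 had a mean under 1 CPM. The median log2 fold change fell with abundance, from 0.363 in genes under 1 CPM to -0.219 in genes over 100 CPM. The list tests did not match genes for abundance, so falls of lists of abundant genes are to be read beside the latter median. The even split of the called genes rests on scaling: with library totals in place of TMM factors, the median of all genes shifted by 0.111 (log2) and 61.6% of the called genes were higher instead of 50%. The camera test called 16 of 26 lists, and 10 of these also passed with an estimated correlation. Besides the 4 lists so marked above, the call was lost for ERK-responsive genes (adjusted p = 0.101 with an estimated correlation) and immediate-early genes (adjusted p = 0.0946). Without replicate 2 of normoxia shControl the ATF4 and immediate-early lists also lost their call at the preset correlation, each at an adjusted p of 0.0501.

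In shRIPOR3 cells hypoxia again raised the HIF targets, by less. Of the 29 targets 26 rose and 3 did not pass the test, with a median log2 fold change of 1.01. NDRG1 rose by 2.75 ± 0.0407, BNIP3 by 1.70 ± 0.0447, DDIT4 by 1.81 ± 0.0501 and the histone demethylase gene KDM3A by 1.21 ± 0.0367. HIF1A fell by 0.74 on the log2 scale, EPAS1 rose by 0.49 ± 0.0795 and METTL3 fell by 0.41. The largest increases after the abundance filter were PPFIA4 (4.13 ± 0.145), NDRG1, ALDOC (2.40 ± 0.143), RASSF4 (2.33 ± 0.115) and PFKFB4 (1.99 ± 0.0692). The largest decreases were the pseudogene LSM12P1 (-1.25 ± 0.126), ANKRD29 (-1.08 ± 0.127), the smooth-muscle actin-binding gene TAGLN (-1.04 ± 0.063), COX6C (-0.92 ± 0.153) and the antisense transcript APCDD1L-AS1 (-0.89 ± 0.0786). COX6C varied widely between the hypoxia shRIPOR3 replicates (368 ± 134 CPM, n = 3). LSM12P1 may share reads with its parent gene, and APCDD1L-AS1 with its antisense partner, because no strand setting was stated.

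Several metabolic, matrix and growth lists moved in the direction seen in shControl cells, and cholesterol synthesis did not, with 6 of 23 genes higher and 9 lower (list adjusted p = 0.977). G2/M genes fell in 16 of 24 cases and rose in 4 (list adjusted p = 0.128), and the ATF4 list had 8 of 19 higher and 6 lower (7 lower adjusted over the list alone; list adjusted p = 0.609). Glycolysis rose in 16 of 19 genes with 1 lower, and extracellular matrix genes in 23 of 26, including THBS1 (1.26 ± 0.0349) and COL4A1 (1.24 ± 0.04). Oxidative phosphorylation fell in 24 of 27, all 28 ribosomal protein genes fell (median -0.47) and ribosome biogenesis fell in 14 of 22 with 3 higher (15 and 3 adjusted over the list alone). The last list had an adjusted p of 0.144 with an estimated correlation. The tricarboxylic acid cycle fell in 10 of 14 genes and rose in 1. DNA replication fell in 18 of 25 and rose in 4, a call that was lost with an estimated correlation (adjusted p = 0.302) and under 5 other alternatives, with adjusted p between 0.0539 and 0.224. In all, edgeR called 8702 genes, 3944 higher and 4758 lower, with 501 up and 37 down by at least 2-fold. Library totals in place of TMM factors moved the median by 0.123 and made 63.4% of the called genes higher instead of 45.3%. Camera called 12 of 26 lists, 8 of them also with an estimated correlation. Over the 2 hypoxia comparisons, 7244 genes were called in both, 3203 higher in both and 3850 lower in both, where independent lists would share 1279 and 1541.

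In normoxia the RIPOR3 hairpin raised genes of the amino acid stress response and lowered interferon-stimulated and mitotic genes. Of 19 genes on the ATF4 and amino acid response list 16 rose and none fell (median 0.71), including ATF4 itself (0.82 ± 0.034), the serine synthesis enzyme PSAT1 (0.96 ± 0.0392), the amino acid transporter chain SLC3A2 (0.85 ± 0.0386) and DDIT3 (1.23 ± 0.0624). Of 24 interferon-stimulated genes 11 fell and 1 rose, with IFIT1 at -1.62 ± 0.0645, IFIT2 at -1.44 ± 0.0543 and OASL at -2.22 ± 0.102. Of 24 G2/M genes 20 fell by small amounts and 1 rose (median -0.22), such as the proliferation marker MKI67 (-0.52 ± 0.0366) and BIRC5 (-0.50 ± 0.0383). HIF1A was lower by 0.80 on the log2 scale (-0.80 ± 0.0388, adjusted p = 3.72e-14), EPAS1 by 0.47 (-0.47 ± 0.0884), and METTL3 was 0.11 ± 0.0409 higher (adjusted p = 0.026). The METTL3 call was lost in DESeq2 (adjusted p = 0.0585), with no low-count filter (0.0509), with only the 2 groups compared (0.121), and without replicate 2 of normoxia shControl (0.104) or replicate 3 of normoxia shRIPOR3 (0.11). Over all alternatives its adjusted p ran from 0.0288 to 0.121.

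Several genes fell steeply. RABL6, on chromosome 9 from 136807943 to 136841187 (GRCh38), went from 165 ± 2.55 to 31.0 ± 2.40 CPM (log2 -2.40 ± 0.0586, adjusted p = 1.32e-19). The trypsinogen gene PRSS2 had a log2 fold change of -4.13 ± 0.162, the organic anion transporter SLCO4A1 -2.90 ± 0.121, the tetraspanin CD82 -2.81 ± 0.132, PAEP -2.64 ± 0.136, the cystatin CST4 -2.52 ± 0.164 and the GTPase DNM1 -2.47 ± 0.1. The largest increases were KRTAP2-3 (2.88 ± 0.147), the kinase DCLK1 (2.20 ± 0.0949), the fatty acid-binding protein FABP4 (2.16 ± 0.121), SCG5 (2.09 ± 0.0817), the monocarboxylate transporter SLC16A1 (2.04 ± 0.142), the long noncoding RNAs UCA1 (2.00 ± 0.0423) and LINC00910 (1.88 ± 0.105), and the collagenase MMP1, which rose from 1045 ± 17.2 to 3819 ± 62.5 CPM (1.87 ± 0.0386). PRSS2, CST4 and KRTAP2-3 belong to families of near-identical genes, so their counts may include reads of relatives.

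Smaller shifts ran through whole lists. Cholesterol synthesis fell in 16 of 23 genes (17 adjusted over the list alone) and rose in none, with HMGCS1 at -0.63 ± 0.0418 and LSS at -0.52 ± 0.0486, although the list had an adjusted p of 0.0774 with an estimated correlation. Ribosomal protein genes rose in 23 of 28 cases and fell in 2, with RPLP1 the lower (-0.61 ± 0.0392) (adjusted p = 0.333 with an estimated correlation). Oxidative phosphorylation rose in 16 of 27 (adjusted p = 0.0623 with an estimated correlation), and ribosome biogenesis rose in 12 of 22 and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.333 with an estimated correlation). HIF targets split into 10 lower, 3 higher and 16 uncalled, with NDRG1 lower (-1.22 ± 0.0409) and the peptide hormone gene ADM higher (1.20 ± 0.048), and the list lost its call with an estimated correlation (adjusted p = 0.208). In all, edgeR called 7151 genes, 3934 higher and 3217 lower, of which 266 rose and 398 fell at least 2-fold. Camera called 8 of 26 lists, and 3 of them, the ATF4, interferon and G2/M lists, also passed with an estimated correlation.

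In hypoxia the HIF targets themselves were lower in shRIPOR3. Of 29 targets 26 were lower in shRIPOR3 than in shControl and 1 was higher (27 and 1 adjusted over the list alone), with a median log2 fold change of -0.71. NDRG1 stood at 483 ± 11.2 CPM against 1972 ± 30.7 (log2 -2.03 ± 0.0369, adjusted p = 3.16e-22), CA9 at 1.49 ± 0.163 against 15.6 ± 0.729 CPM (-3.36 ± 0.0955), ANGPTL4 at -2.67 ± 0.103, BHLHE40 at -2.06 ± 0.0388 and PFKFB4 at -1.41 ± 0.0434. Glycolytic genes followed, with 15 of 19 lower and 1 higher, such as ALDOC (-1.98 ± 0.0717), ENO2 (-1.13 ± 0.0434) and PGK1 (-0.82 ± 0.0352). Matrix genes were lower in 17 of 26 cases and higher in 4, with PLOD2 at -1.57 ± 0.0355 and COL6A1 at -1.45 ± 0.0398. HIF1A mRNA did not differ detectably (-0.07 ± 0.0389, adjusted p = 0.109), EPAS1 was lower (-1.12 ± 0.0599) and METTL3 was higher (0.21 ± 0.0388).

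Lipid, interferon and amino acid genes moved in the direction seen in normoxia. Cholesterol synthesis fell in 21 of 23 genes (median -0.55), with HMGCS1 at -1.32 ± 0.0362 and INSIG1 at -1.35 ± 0.0492. Interferon-stimulated genes fell in 14 of 24 cases and rose in 2, with IFIT2 at -1.29 ± 0.0476 and ISG20 at -1.72 ± 0.0746. The ATF4 list rose in 15 of 19 and fell in 3, with PSAT1 at 1.00 ± 0.0365, SHMT2 at 0.77 ± 0.0407 and VLDLR going the other way (-1.10 ± 0.0514). Oxidative phosphorylation rose in 22 of 27 genes (23 adjusted over the list alone, median 0.27), the tricarboxylic acid cycle rose in 10 of 14 and fell in 1, and ribosomal protein genes rose in 24 of 28 and fell in 1 (adjusted p = 0.217 with an estimated correlation). Ribosome biogenesis rose in 17 of 22 with 1 lower (median 0.42), such as RRP9 (1.01 ± 0.0482) and POLR1B (0.72 ± 0.0351). Replication-dependent histone genes rose in 6 of 9 tested and fell in 1, including HIST1H1C (1.53 ± 0.0477) and HIST1H2AC (1.72 ± 0.082). With adjustment over the list alone 7 rose. Many histone mRNAs lack a poly(A) tail, and histone genes share reads with near-identical copies.

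At the extremes stood PRSS2 (-3.78 ± 0.119), PAEP (-3.45 ± 0.0891), CST4 (-3.11 ± 0.125) and SLCO4A1 (-3.10 ± 0.0918), together with the NADPH oxidase NOX5 (-3.73 ± 0.13) and CST1 (-3.10 ± 0.103). DCLK1 (2.16 ± 0.0851), FABP4 (2.13 ± 0.106), KRTAP2-3 (2.05 ± 0.101), LINC00910 (1.77 ± 0.084), the neurotrophin BDNF (1.62 ± 0.0662) and ID3 (1.55 ± 0.0823) were the highest besides the histones. Among markers of other cell types, 4 blood and endothelial genes could be tested, and PECAM1 (-1.87 ± 0.119), CDH5 (-1.79 ± 0.11) and LYZ (-1.26 ± 0.345) were lower in shRIPOR3, with shControl levels of 4.84 ± 0.307, 8.29 ± 0.274 and 0.447 ± 0.127 CPM (n = 3). In normoxia PECAM1 was lower as well (-2.12 ± 0.154), and the list was not called there (adjusted p = 0.128). That list had an adjusted p of 0.0218 and of 0.0675 with an estimated correlation. edgeR called 9689 genes, 4804 higher and 4885 lower, with 219 up and 768 down by at least 2-fold, and camera called 15 of 26 lists. With median-of-ratios factors 51.8% of the called genes were higher, and with upper-quartile scaling 49.7%. With an estimated correlation the calls were lost for the FOXO (adjusted p = 0.0591), mesenchymal (adjusted p = 0.0636), G2/M (adjusted p = 0.103) and ribosomal protein lists (adjusted p = 0.217). G2/M genes fell in 14 of 24 cases and rose in 5.

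The knockdown effects in the 2 oxygen conditions overlapped, and they share no library. Both comparisons called 5827 genes, of which 2955 were higher in both, 2599 were lower in both and 273 went in opposite directions. Independent lists of these sizes would share 1208 higher and 1004 lower genes. Across the 15648 genes the 2 sets of log2 fold changes had a Pearson r of 0.693 and a Spearman correlation of 0.671, where genes are not independent replicates. DNM1 and RABL6 were among the 292 genes that fell at least 2-fold in both. MMP1 rose in both, by 1.87 ± 0.0386 in normoxia and 0.90 ± 0.0375 in hypoxia.

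The interaction asked whether the hypoxia response itself differed between the lines. It did so for HIF targets, of which 25 of 29 had a significantly smaller response in shRIPOR3 (26 adjusted over the list alone) and none a larger one, with a median interaction of -0.54 (log2). The slope of the shRIPOR3 on the shControl response was 0.673 for HIF targets, 0.702 for glycolysis, 0.657 for matrix genes and 0.286 for cholesterol synthesis. For all 5074 genes that rose in shControl the slope was 0.565, which choosing genes for rising can lower. By these slopes HIF targets were not weakened more, in proportion, than rising genes in general. VEGFA had an interaction of -0.70 ± 0.0541, NDRG1 of -0.81 ± 0.0542, BNIP3L of -0.72 ± 0.0591 and ANGPTL4 of -2.08 ± 0.357. IGFBP3, which binds insulin-like growth factors, rose from 46.4 ± 0.696 to 182 ± 3.85 CPM in shControl and from 66.2 ± 1.88 to 75.4 ± 0.986 CPM in shRIPOR3 (-1.78 ± 0.0537, adjusted p = 6.62e-17). The collagen crosslinking enzyme LOX (-1.88 ± 0.162), MAP3K7CL (-1.89 ± 0.202) and TCAF2 (-1.86 ± 0.447) followed. TCAF2 lost its call without replicate 3 of normoxia shRIPOR3 (adjusted p = 0.0628), and over all alternatives its adjusted p ran from 0.000246 to 0.0628.

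Interactions in the other direction were fewer at 2-fold or more, 33 genes against 158, or 14 against 72 in DESeq2. ANXA10 (interaction 1.24 ± 0.15) fell under hypoxia in shControl (-1.42 ± 0.118) and did not pass the test in shRIPOR3 (-0.18 ± 0.0924). CD22 had an interaction of 1.18 ± 0.111 and MRM1 of 0.92 ± 0.166. The HIF1A interaction was 0.73 ± 0.0549 and that of EPAS1 was -0.65 ± 0.108, whereas that of METTL3 was 0.10 ± 0.0564 (adjusted p = 0.231, or 0.043 without replicate 2 of hypoxia shControl, the lowest of its alternatives). MIR210HG (2.56 ± 0.567) rests on a normoxia level of 0.0606 ± 0.013 CPM in shRIPOR3, and that of SERF1B (2.26 ± 0.682) was 1.17 without replicate 2 of normoxia shControl. Glycolysis (11 of 19 lower and 1 higher, 12 lower adjusted over the list alone, median -0.23), matrix genes (12 of 26 lower and 2 higher, 14 lower over the list alone, median -0.30) and cholesterol synthesis (15 of 23 lower and 1 higher, 16 lower over the list alone, median -0.35) shared the direction of the HIF targets. Ribosome biogenesis went the other way, with 13 of 22 higher and none lower (median 0.26), and so did oxidative phosphorylation, with 9 of 27 higher and none lower. In all, edgeR called 3624 genes, 1704 higher and 1920 lower. Which direction holds more genes rests on scaling, as 54.3% were higher with median-of-ratios factors, 51% with upper-quartile scaling and 51.2% with library totals. Leaving out 1 library gave 1409 to 2219 higher and 1394 to 1853 lower genes. Camera called 15 of 26 lists, 12 of them also with an estimated correlation. The calls of ERK-responsive genes (adjusted p = 0.199 with an estimated correlation), DNA replication (0.115) and NF-kB genes (0.0741) were lost, and ERK-responsive genes also lost theirs without replicate 2 of hypoxia shControl (adjusted p = 0.0657). Of the 1245 genes that rose at least 2-fold in shControl, 419 had a lower and 2 a higher interaction, and of the 501 that did so in shRIPOR3, 88 had a lower and 11 a higher interaction.

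**Figure D3:**
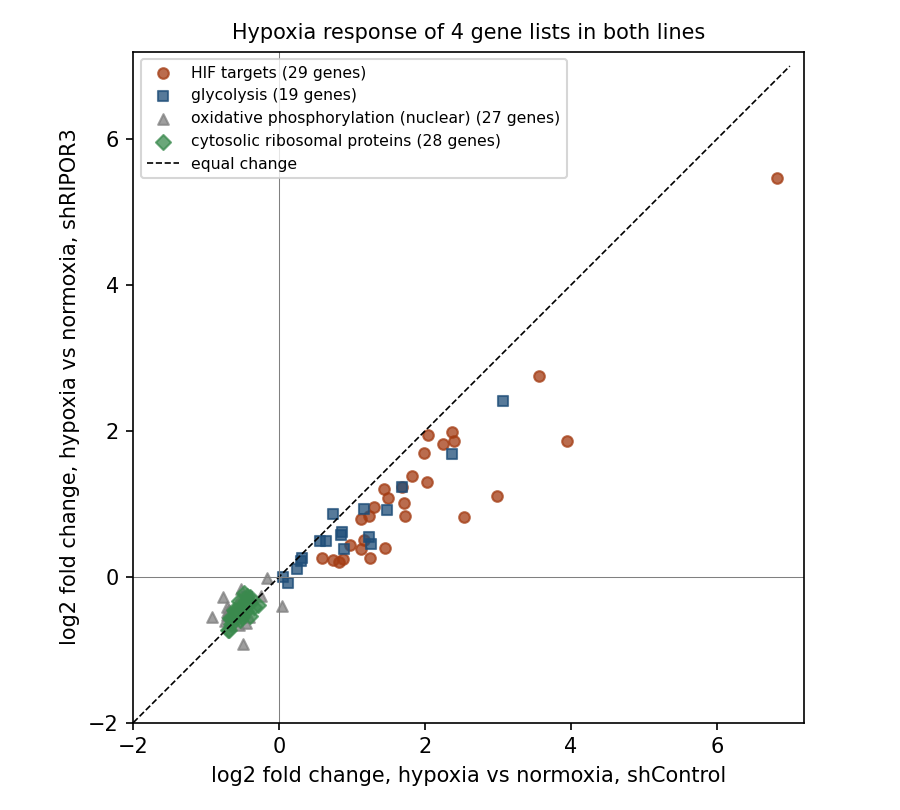
Log2 fold change under hypoxia in shControl (horizontal axis) and in shRIPOR3 (vertical axis) for the genes of 4 lists, with the line of equal change. HIF targets have a median of 1.68 in shControl and 1.01 in shRIPOR3, and ribosomal protein genes lie below 0 in both.

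**Figure D4:**
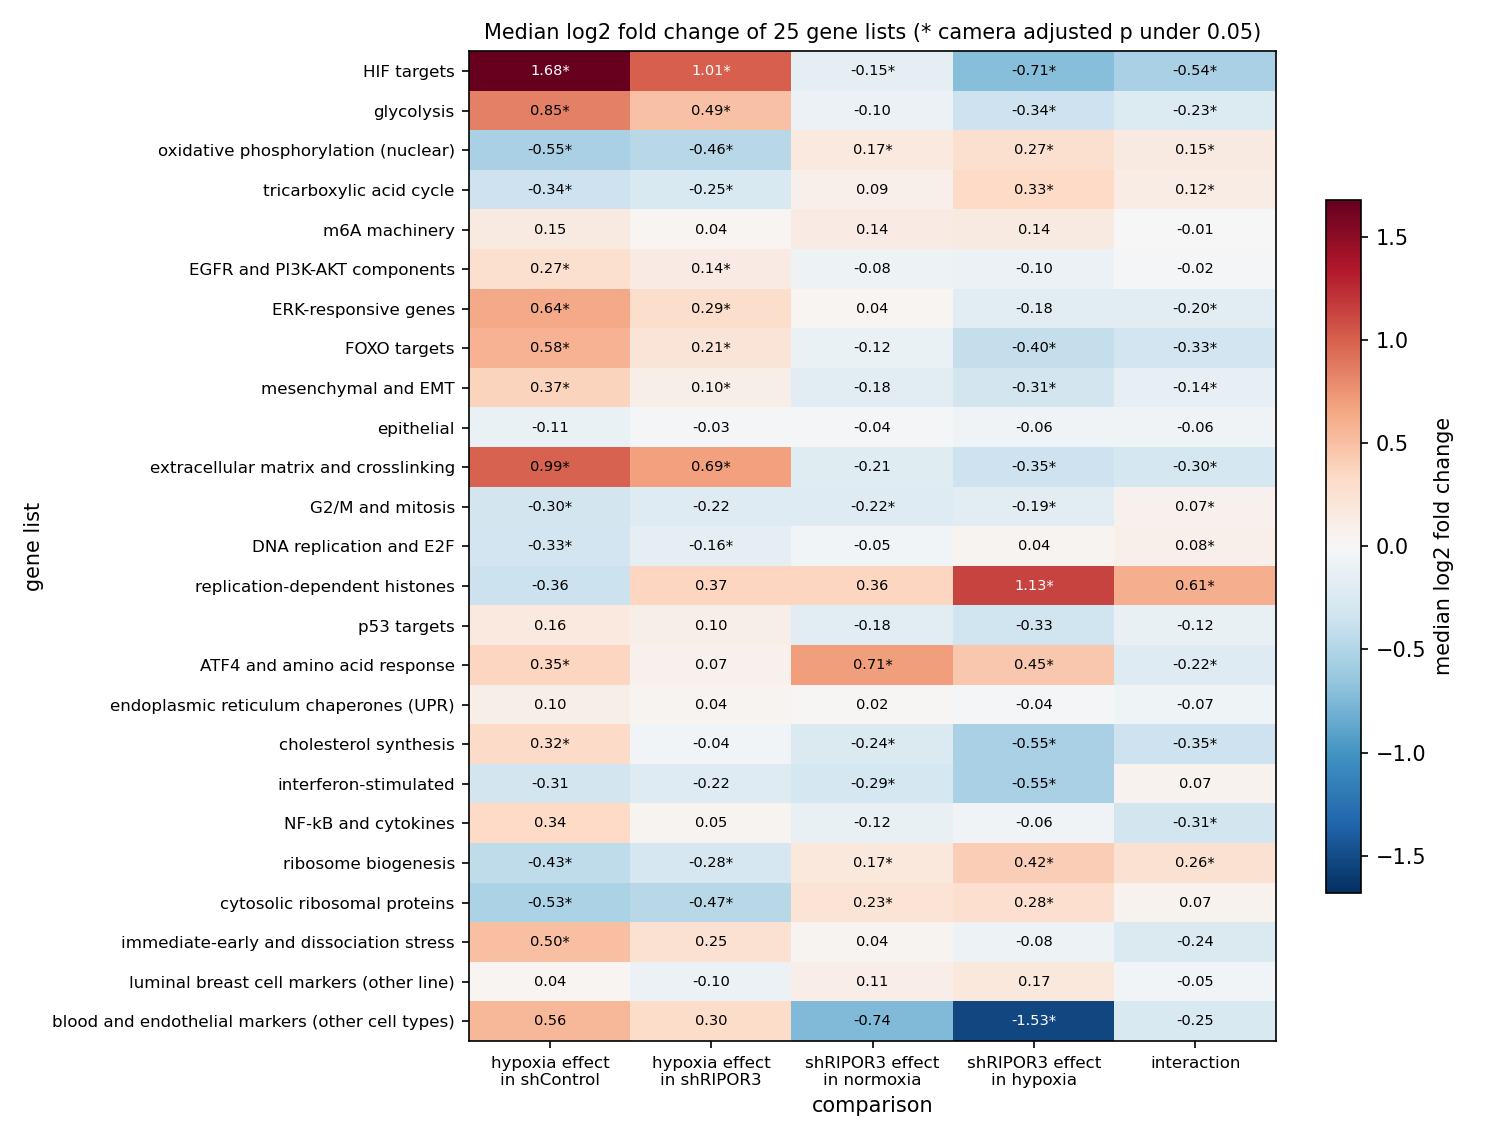
Median log2 fold change of each of 25 gene lists (rows) in the 4 comparisons and the interaction (columns), with an asterisk where camera gave an adjusted p under 0.05. The HIF targets read 1.68, 1.01, -0.15, -0.71 and -0.54 from left to right.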

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

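Thinning to one library total was chosen only after the results were seen, and the other tests in this part were planned. Each value here was set apart because the hypoxia effect differed between shControl and shRIPOR3 in edgeR's interaction test at an adjusted p under 0.05. This held for 3624 genes, with 1704 higher and 1920 lower interactions, 33 of them at least 2-fold higher and 158 at least 2-fold lower (14 and 72 in DESeq2). With median-of-ratios factors 54.3% of the called genes were higher.

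By list, the median interaction (log2) was -0.54 for HIF targets, -0.35 for cholesterol synthesis, -0.33 for FOXO targets, -0.31 for NF-kB genes, -0.30 for extracellular matrix genes, -0.23 for glycolysis, -0.22 for the ATF4 list, -0.20 for ERK-responsive genes and -0.14 for mesenchymal genes. It was 0.07 for G2/M genes, 0.08 for DNA replication, 0.12 for the tricarboxylic acid cycle, 0.15 for oxidative phosphorylation, 0.26 for ribosome biogenesis and 0.61 for histones. With an estimated correlation the calls of NF-kB genes (adjusted p = 0.0741), ERK-responsive genes (adjusted p = 0.199) and DNA replication (adjusted p = 0.115) were lost.

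Among the 112 genes named in these texts 75 had such an interaction, with SE from 0.0473 for ATF4 to 0.682 for SERF1B. Below -1 were ANGPTL4 (-2.08), MAP3K7CL (-1.89), LOX (-1.88), TCAF2 (-1.86), IGFBP3 (-1.78), SPAG4 (-1.31), SCG5 (-1.20), CDH5 (-1.05), CCNG2 (-1.04) and ISG20 (-1.03). TCAF2 lost its call without replicate 3 of normoxia shRIPOR3 (adjusted p = 0.0628). Between -1 and -0.70 were MMP1 (-0.97), SLC16A1 (-0.94), VLDLR (-0.92), INSIG1 (-0.88), KRTAP2-3 (-0.83), NDRG1 (-0.81), PAEP (-0.81), PGK1 (-0.81), CST1 (-0.80), PLOD2 (-0.79), RASSF4 (-0.79), ADM (-0.74), BNIP3L (-0.72), UCA1 (-0.70) and VEGFA (-0.70). Smaller negative values were those of HMGCS1 (-0.69), ENO2 (-0.68), HK2 (-0.68), ALDOC (-0.67), CDKN1A (-0.66), EPAS1 (-0.65), IL1B (-0.64), CTGF (-0.63), LSM12P1 (-0.61), EGFR (-0.58), BHLHE40 (-0.54), FN1 (-0.45), IRS2 (-0.45), SLC2A1 (-0.45), DDIT4 (-0.43), APCDD1L-AS1 (-0.41), IGF2BP3 (-0.40), PFKFB4 (-0.38), COL7A1 (-0.36), TAGLN (-0.36), JUN (-0.32), BNIP3 (-0.29), ATF4 (-0.28), COL4A1 (-0.25), KDM3A (-0.24) and DUSP4 (-0.21). Positive values were those of ATP5A1 (0.19), BIRC5 (0.19), SUCLG1 (0.26), CCNB1 (0.27), RABL6 (0.29), EIF2B3 (0.32), IDH3A (0.32), POLR1B (0.34), ATP5G1 (0.36), COQ3 (0.39), CHORDC1 (0.40), HIST1H1C (0.43), SMARCD3 (0.51), IFIT1 (0.58), OASL (0.64), HIST1H2AC (0.65), ID3 (0.65), RRP9 (0.70), HIF1A (0.73), MRM1 (0.92), CD22 (1.18), ANXA10 (1.24), SERF1B (2.26) and MIR210HG (2.56). The value of SERF1B was 1.17 without replicate 2 of normoxia shControl.

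The smaller response to hypoxia in shRIPOR3 was weighed as a technical effect. Depth is argued against, as the HIF list stayed called after thinning to one library total (adjusted p = 2.598e-27) and its median interaction moved by -0.022. An exchange of libraries between the 2 hypoxia groups is argued against, as 0 of the 6 hypoxia libraries lay nearer the other group in the first 2 principal components. For the 5074 genes that rose in shControl, one common ratio of 0.565 is argued against, as 27.2% of them departed from it, 889 above and 489 below. The ratio was fitted to genes chosen for rising in shControl, which can lower it. A uniform weakening of the whole response would need one ratio for these genes too, so it is argued against as far as they go. Genes that fell were not tested in this way. An effect of the knockdown on the hypoxia response, in part or as a whole, may be a biological explanation, as a hypothesis. Seed-type pairing of the single hairpin, weighed among the other observations, stays open beside it.

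Other splits of the libraries were counted for each number of genes. For the 4 pairwise comparisons 6 libraries allow 10 splits, of which 1, the real one, gave as many genes, and these are too few splits for a share under 0.05. The real counts in edgeR were 10142, 8702, 7151 and 9689, and the highest of the other splits was 0 in each, with 543, 525, 923 and 323 genes at an unadjusted p under 0.05. For the interaction 100 of 200 possible splits were drawn and 3, the real one included, gave at least 3624 genes, with 5475 in the highest other split. This count does not decide on chance. Splits that break up the hairpin groups at both oxygen levels put the effect of the hairpin into the spread within groups, and the highest of them gave 0 genes in edgeR and 350 at an unadjusted p under 0.05. Only 15 other drawn splits kept the knockdown groups at 1 or both oxygen levels, too few for a share under 0.05, and 2 of these gave as many genes as the real one. Such splits carry the knockdown effect of the level kept into the interaction, so they do not measure chance and more of them would not decide it.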

How the results depend on the processing

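Library totals and thinning were chosen after seeing the data, and every other alternative was planned. Under all of them 8676 values of named genes kept direction and side of the threshold, 85 lost their call, 1 gained one and 1 reversed: XBP1 under hypoxia in shRIPOR3 was 0.01547 with library totals (-0.11 as analysed, adjusted p over all alternatives 0.0135 to 0.784). Of list results 2117 stayed, 33 lost and 60 gained a call. The stricter filter gave 45 genes 2-fold lower in hypoxia in shControl, 316 higher and 7 lower at 2-fold in hypoxia in shRIPOR3, 149 higher at 2-fold for the normoxia knockdown, and 125 and 508 for the hypoxia knockdown. It tests fewer weak genes and removed RIPOR3, which has no value there. No filter gave 64 2-fold lower in hypoxia in shRIPOR3 and 359 2-fold higher for the hypoxia knockdown. Library totals gave 64 2-fold lower in hypoxia in shControl, 3159 lower, 772 2-fold higher and 23 2-fold lower in hypoxia in shRIPOR3, and 2562 lower in both hypoxia comparisons. DESeq2 gave 14 and 72 interaction genes at 2-fold, and a threshold of 0.01 gave 2185 (1024 higher, 1161 lower, 12 and 76 at 2-fold), as a stricter threshold must. An estimated correlation gave 10 lists in hypoxia in shControl and 3 in the normoxia knockdown, and fry, which asks another question, gave 24, 19 and 24 lists in hypoxia in shRIPOR3 and the normoxia and hypoxia knockdowns. Where no reason is given, the cause was not tested. Leaving out 1 library gave 2994 to 3730 interaction genes, and a replicate block 3595. RIPOR3 ran from -6.07 to -3.27 in the normoxia knockdown and from 1.08 to 3.88 in the interaction, as its counts are few.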

Other observations

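None of the tests in this part was chosen only after its result was seen, except thinning to one library total, the rank of purine-only 7-mers in hypoxia and the run that DNM1 shares with RIPOR3. Signalling genes moved with hypoxia. Of 24 EGFR and PI3K-AKT components 15 rose and 3 fell in shControl, and 13 rose and 2 fell in shRIPOR3, with the receptor EGFR up by 1.57 ± 0.0374 and 1.00 ± 0.037 and the insulin receptor substrate IRS2 by 2.20 ± 0.0715 and 1.74 ± 0.06. ERK-responsive genes rose in 14 of 19 cases and fell in 3 in shControl (15 rose adjusted over the list alone; adjusted p = 0.101 with an estimated correlation) and rose in 15 and fell in 2 in shRIPOR3 (adjusted p = 0.129 with an estimated correlation), such as the phosphatase DUSP4 (0.80 ± 0.0349 and 0.60 ± 0.0352). FOXO targets rose in 13 of 17 genes and fell in 1 in shControl, rose in 10 and fell in 2 in shRIPOR3, and 14 of 17 were lower and 3 higher in the hypoxia knockdown comparison, with the cyclin CCNG2 at -2.14 ± 0.0627 and CITED2 at 0.73 ± 0.0394 (adjusted p = 0.0591 with an estimated correlation). Mesenchymal genes rose in 12 of 19 cases and fell in 3 in shControl, and rose in 9 and fell in 5 in shRIPOR3 (adjusted p = 0.0688 with an estimated correlation). In the hypoxia knockdown comparison 13 of these 19 were lower and 5 higher (adjusted p = 0.0636 with an estimated correlation), with fibronectin FN1 at -1.35 ± 0.0365 and the adhesion molecule L1CAM at -2.06 ± 0.0891. Immediate-early genes rose in 11 of 18 cases and fell in 3 in shControl (12 rose adjusted over the list alone), with JUN at 1.08 ± 0.0382 (adjusted p = 0.0946 with an estimated correlation).

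Several lists were not called by camera in the 4 pairwise comparisons, although single members moved. Of 19 m6A genes 11 rose and 5 fell under hypoxia in shControl, with METTL14, the partner of METTL3, at -0.47 ± 0.0427 and the demethylase ALKBH5 at 0.53 ± 0.0488 (list adjusted p = 0.437). The m6A reader IGF2BP3 was lower with the knockdown in normoxia (-0.49 ± 0.0438) and in hypoxia (-0.89 ± 0.0386). Of 17 p53 targets 11 were lower (12 adjusted over the list alone) and 3 higher in the hypoxia knockdown comparison (list adjusted p = 0.0619), with the cell cycle inhibitor CDKN1A at -1.38 ± 0.0538. That list was called with no low-count filter (adjusted p = 0.0185), without replicate 1 of hypoxia shControl (adjusted p = 0.0379) and without replicate 2 of hypoxia shRIPOR3 (adjusted p = 0.0454). Endoplasmic reticulum chaperones went both ways there, 5 higher and 6 lower of 16 (list adjusted p = 0.794), with HSP90B1 at -0.60 ± 0.0418. Of 14 epithelial genes 2 were higher and 5 lower (list adjusted p = 0.604), with the claudins CLDN4 (-1.03 ± 0.11) and CLDN7 (-1.29 ± 0.144) lower, and of 9 luminal markers 1 was higher and 1 lower (list adjusted p = 0.801). NF-kB genes were lower in 8 of 18 cases and higher in 5 (list adjusted p = 0.124, or 0.0326 with the stricter filter), with IL1B at -1.66 ± 0.065, and this list was called in the interaction (adjusted p = 0.0741 with an estimated correlation).

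Sequence sites were weighed for the genes that fell with the knockdown, because a single hairpin was used and its sequence is not known. Over 9565 genes, carriers of the 7-mer AAGAAGA in the 3 prime UTR had the lowest z of 16150 7-mers in normoxia (-10.16, where 100 permutations reached -4.99) and rank 1 again in hypoxia (-10.57), and the site occurs once in 3 of 6 RIPOR3 transcripts. Presence in RIPOR3 is weak evidence, as CTGCCCC and CTGCTCC, also among the 7-mers of low z, each occur in 5 of the transcripts. CCCACCC, which occurs in none, also passed the permutations in normoxia (z -5.74). For purine-rich UTRs in general, a median rank of purine-only 7-mers without a shared 6-mer within the first 5% of all 7-mers in normoxia was set beforehand as the bound for, and beyond 25% as the bound against. They are argued against in normoxia, at 30.6% (95% interval 26.9% to 37.8%, which takes the 7-mers as independent), and stay open in hypoxia, at 17.7%. This set of 7-mers leaves out AGAAGAA and GAAGAAG, which rank 2 and 3 in both comparisons, so it does not speak to repeats of GAA. Seed-type pairing of the hairpin with other mRNAs may account for part of the decreases. The shift of carriers, adjusted for UTR length, GC content and expression, was -0.0943 in normoxia and -0.1194 in hypoxia (log2). Unadjusted medians for 0, 1, 2 and 3 or more UTR sites were 0.0452, -0.0141, 0.007 and -0.0514 in normoxia, without a steady trend. In hypoxia they were 0.059, -0.0704, -0.1001 and -0.1407. For sites in the whole mRNA the medians fell steadily, through 0.0864, 0.0364, 0.0023 and -0.0796 in normoxia and 0.1302, 0.0322, -0.0145 and -0.1494 in hypoxia. These medians were not adjusted for mRNA length, which bears on the number of sites. Of 90 scanned genes that fell at least 2-fold in both, 61 carry a site in their mRNA. Genes matched on mRNA length alone had a median of 52 (21 of 1000 draws reached 61). Of the 90, 32.2% carry none, PRSS2, SLCO4A1, CD82 and PAEP among them. An effect of lower RIPOR3 thus stays open, and no biological explanation was tested apart from it. DNM1 shares with RIPOR3 a run of 17 bases that holds the 7-mer. No gene shares a longer one in a window set around this run, while 1470 genes share a run as long or longer somewhere in RIPOR3.

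The excess of 2-fold increases over decreases under hypoxia in shControl was weighed as a technical effect. Depth is argued against, as 1003 genes rose and 86 fell at least 2-fold after thinning to one library total, a ratio of 11.7. A larger share of noncoding RNA is argued against as the only source, as the ratio was 11.6 among protein-coding genes alone. Antisense genes (median 0.5) and lincRNA genes (0.319) did rise more than protein-coding genes (-0.0132), and processed pseudogenes did not (-0.276). Reads of unspliced RNA could also fall on protein-coding genes, so this ratio does not decide on them. Genes of families expected to be silent (olfactory and taste receptors, defensins and keratin-associated proteins) summed to 3.26 ± 0.574 CPM in normoxia and 6.58 ± 0.36 CPM in hypoxia in shControl (n = 3), a ratio of 2.02. One of them, KRTAP2-3, is expressed, and without it the sums were 2.13 ± 0.465 and 4.16 ± 0.143 CPM, a ratio of 1.95, so a small uniform background cannot be told apart from real expression of these genes. Without KRTAP2-3 the normoxia shRIPOR3 libraries summed to 3.76 ± 0.0665 CPM (n = 3), so these sums also differed between the hairpins. Genes under 1 CPM that rose 2-fold had a median increase per kb of exon 10.7 times the mean increase of the silent families without KRTAP2-3. These genes were chosen for rising and the silent families were not, so the ratio does not decide how much such a background added to them. The response to hypoxia itself stays open as the biological explanation, as a hypothesis.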
